A study of Mus musculus with 27 samples.

How the data were processed

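RNA-seq was carried out on sorted mouse liver cells after hepatobiliary reprogramming, the conversion of injured hepatocytes towards cells that express bile duct genes. Per the labels' protocols, mice of 4 to 5 weeks were injected behind the eye with an adeno-associated virus. It carried a guide RNA under the U6 promoter and Cre recombinase under the hepatocyte-specific TBG promoter. A diet with the porphyrinogenic agent DDC at 0.1%, which injures bile ducts and blocks bile flow, began 1 week after injection and, per the series' design text, lasted 8 weeks. GFP-positive cells were sorted, and surface CD24 separated a negative fraction (called early here) from a positive fraction (called late), so Cd24a differs between the fractions by sorting and is not reported as a result. The genotypes were the empty vector (EV), a guide against Kdm2a (Kdm2aKO) and a guide against Nsd1 (Nsd1KO). Kdm2a is a demethylase of lysine 36 of histone H3 and Nsd1 a methyltransferase of the same residue. The guide sites were not given in the sources used here.

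The authors deposited raw counts per gene symbol for 27 polyA RNA libraries. Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on build GRCm39; versions, annotation, strand setting and the treatment of reads with several matches were not given in the sources used here. Values of gene families with near-identical copies, such as Cyp2, Cyp4a, Sult, Ugt2b, H2, Saa and Mup, and of genes that overlap on opposite strands, are therefore uncertain. Of the 53599 symbols, 95.8% were found in naming tables of assembly GRCm38.p6 (GENCODE M21). That reference was used only for names, gene order and transcript sequence, and no coordinates are given. The deposited sample sheet holds no measurement and was not used for grouping.

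Each library was assigned to a genotype, stage and batch from its labels. Kdm2aKO was in batch 1 and Nsd1KO in batch 2, so each was compared only with the EV libraries of its own batch. The labels do not state that the replicates of a group came from separate mice, so p-values measure the spread between these samples. No libraries within a group were closer than sampling noise, and all were counted.

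Total counts per library ran from 32236295 to 39471220 in batch 1 and from 38164234 to 67582926 in batch 2. Where a group had no count of a gene, the fold was computed against a floor of 3 counts over the group and is a lower limit. Ratios against a group with 1 to 3 counts carry a 95% interval. These floors and intervals cover counting error only. The 10 most abundant genes took 14.9 to 20.6% of the counts of early libraries and 8.37 to 13.7% of late ones. TMM factors were 0.686 to 0.793 in early and 1.28 to 1.45 in late libraries.

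Genes were kept by filterByExpr (19278 tested) and fitted with the quasi-likelihood model of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM scaling and 1 mean for each of the 8 combinations of genotype, stage and batch. All 27 libraries shared 1 estimate of the spread. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; "rose" and "fell" refer to that threshold. The 11 comparisons were late against early in EV (mean of both batches), in Kdm2aKO and in Nsd1KO, each knockout against EV at each stage, the genotype by stage interaction of each knockout, and the difference between both knockout effects at each stage. Fold changes are on the log2 scale with their standard error (SE). CPM values are scaled by TMM, and log2 CPM uses a prior count of 2.

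Before the data were examined, 37 gene lists were fixed: hepatocyte and biliary identity, YAP/TEAD targets, Notch, TGF-beta, extracellular matrix, inflammatory, interferon, MHC, proliferation, p53, bile acid, xenobiotic and porphyrin, fatty acid oxidation, cholesterol synthesis, fatty acid and triglyceride synthesis, urea cycle and amino acid catabolism, gluconeogenesis and glycogen, glycolysis, coagulation and complement, pericentral and periportal hepatocyte, fetal liver, unfolded protein response, H3K36 methylation enzymes, Polycomb complexes and Polycomb targets, dissociation stress, markers of macrophages, neutrophils, lymphocytes, endothelial, stellate, erythroid and mesothelial cells, mitochondrially encoded genes and ribosomal proteins. Some lists share members; hepatocyte identity shares 7 with the urea cycle list and 4 with the coagulation list. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

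Named genes were chosen by a rule fixed in advance. It took Kdm2a and Nsd1 throughout, and per comparison the 6 largest rises and 6 largest falls, not all of which are printed. These had to pass the threshold, to have an average log2 CPM of at least 1 and, except for interactions and differences of effects, to show no overlap between the compared libraries of a batch. Predicted genes without a proper name were skipped, and values of a few genes are not reported here. From each described list it took up to 4 members with the smallest p and an average log2 CPM of at least 1. Y-linked genes and Xist were left out, as were Cd24a, Kdm2a and Nsd1 among the largest changes. A hepatocyte minus biliary score per library, the difference of the mean log2 CPM of both lists, was compared with exact two-sided permutation tests (numpy 2.4.6, scipy 1.17.1, Python 3.11.15; figures with matplotlib 3.10.9). The genotype effects were also correlated over genes with the EV stage change of the other batch, which shares no library with them.

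The alternatives tried were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no filter on low counts, an additive or no batch term, a fit of the compared libraries alone, replicate blocks, each library left out in turn, and for the score the median, another prior count of 0.5 and each list alone. Replicate numbers are shared between early and late libraries. Same-numbered early and late libraries deviated together from their group means in EV (correlations over genes from 0.125 to 0.158 in batch 1 and from 0.174 to 0.213 in batch 2) and in Nsd1KO (0.184 to 0.227), so the numbers were taken to pair these libraries on the evidence of the data.

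The tests were checked on simulated counts with 200 changed genes, drawn from the means and library sizes of the real libraries. For Kdm2aKO early against EV (18745 genes run), 65.7% of 2-fold and 90.9% of 4-fold changes were recovered, with 2.86% of calls false. The shares were 71.6% and 95.5% (3.68% false) for Kdm2aKO late, 64.2% and 89.4% (5.65% false) for Nsd1KO early and 71.6% and 89.4% (8.40% false) for Nsd1KO late.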

Results

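The series measured polyA RNA of GFP-positive liver cells from mice on the DDC diet in 27 libraries. EV was represented by 7 early (CD24-negative) and 7 late (CD24-positive) libraries, 4 of each in batch 1 and 3 of each in batch 2. Kdm2aKO had 4 early and 3 late libraries in batch 1, and Nsd1KO had 3 of each stage in batch 2. Values in parentheses after a gene are its log2 fold change ± SE and the adjusted p (FDR) of edgeR's quasi-likelihood test over 19278 genes, and it is left out for list members, which passed at an adjusted p under 0.05 where said to have risen or fallen. List medians are of log2 fold changes, and counts of members were the same adjusted over the list alone unless a second count is given. Genes outside the naming rule, named because a count was 5 or fewer, were chosen after their values were seen.

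The targeted genes were examined first. Kdm2a was lower in Kdm2aKO early libraries (74.8 ± 5.04 CPM, SD, n = 4) than in EV early libraries of the same batch (114 ± 16.7, n = 4), a log2 fold change of −0.61 (SE 0.097, adjusted p = 7.11e-05). In late cells it was 138 ± 3.37 CPM (n = 3) against 170 ± 13.1 (n = 4), a difference of −0.30 (SE 0.105) that did not pass the test (adjusted p = 0.0748). Nsd1 fell in Nsd1KO early libraries (96.2 ± 4.97 against 140 ± 12.7 CPM, n = 3 each, log2 fold change −0.55, SE 0.101, adjusted p = 0.00149). It also fell in Nsd1KO late libraries (127 ± 5.16 against 172 ± 10.4 CPM, n = 3 each, −0.44, SE 0.101, adjusted p = 0.0338), a call lost when any 1 of the 6 libraries was left out (highest adjusted p = 0.213), with no filter on low counts (0.0851) or with no batch term (0.114). Nsd1 was lower in Kdm2aKO too, at 54.6 ± 3.76 against 125 ± 7.08 CPM in early cells (−1.20, SE 0.0887, adjusted p = 5.44e-10) and 101 ± 4.95 against 147 ± 18.2 CPM in late cells (−0.54, SE 0.0952, adjusted p = 0.000595). Kdm2a did not pass in Nsd1KO (−0.08 with adjusted p = 0.77 in early and −0.03 with adjusted p = 1 in late cells). Between the knockouts, the early effects differed for Kdm2a (−0.53, SE 0.147, adjusted p = 0.0189) and for Nsd1 (−0.65, SE 0.134, adjusted p = 0.00168), both more negative in Kdm2aKO. The call for Kdm2a was lost without Kdm2aKO early 1 (adjusted p = 0.0723) or Nsd1KO early 1 (0.0677), with the compared libraries alone (0.0759) and with no filter (0.0522). In early cells Nsd1 was thus reduced more in Kdm2aKO than in Nsd1KO, so these levels do not settle the genotype labels, which are used as given.

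**Figure D1:**
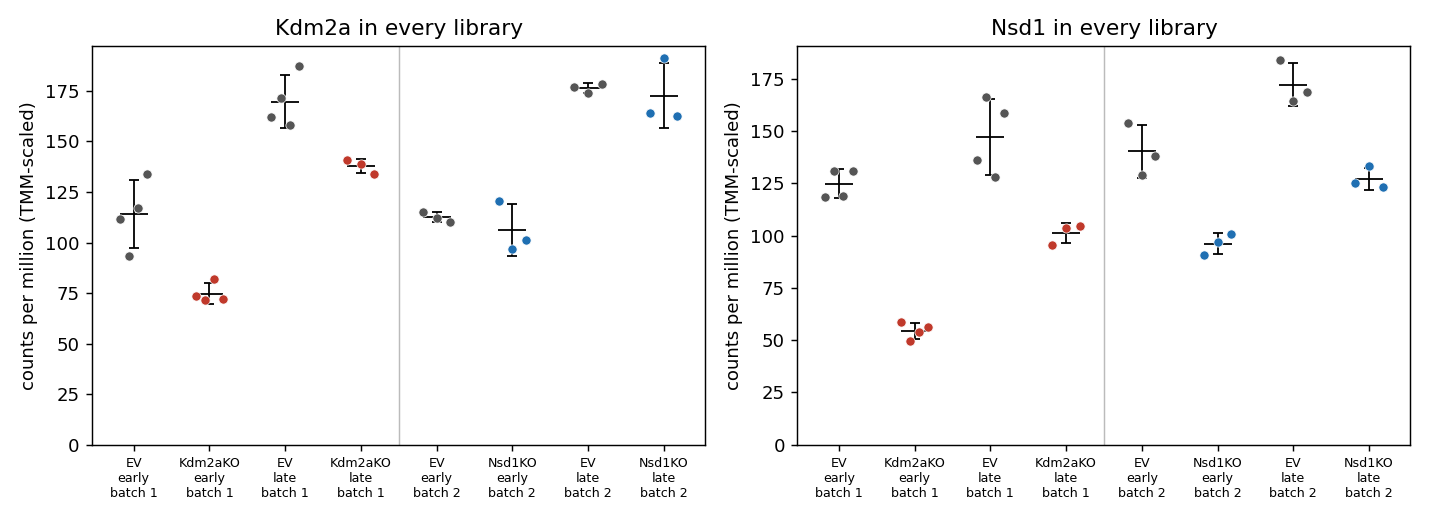
Kdm2a and Nsd1 level (TMM-scaled CPM) in each library (points) of the 8 combinations of genotype, stage and batch, with the mean and SD (bars). Kdm2a averaged 74.8 CPM in Kdm2aKO early against 114 in EV early of batch 1.

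EV late cells were compared with EV early cells (7 against 7 libraries) to show which genes change as injured hepatocytes turn towards the bile duct lineage. Hepatocyte genes were lower and bile duct genes higher in late cells. Of the hepatocyte identity list, 32 of 32 fell, median −4.39, camera adjusted p = 3.31e-16 (p = 0.14 with estimated correlation). Among them were albumin Alb (−3.58 ± 0.222) and Ttr (−2.98 ± 0.15). Of the biliary identity list, 26 of 28 rose and 1 fell, median 3.09, camera adjusted p = 1.94e-09 (p = 0.149 with estimated correlation). Members that rose included the cilium gene Pkhd1 (3.07 ± 0.133) and osteopontin Spp1 (3.13 ± 0.182), while the keratin Krt8 (−0.29 ± 0.109) fell. In total 13664 genes passed (7294 higher and 6370 lower in late cells), 8428 of them by at least 2-fold. Within batches the counts were 11762 in batch 1 and 11230 in batch 2, with 5008 genes higher and 5049 lower in both and 1 in opposite directions. Another scaling moved the median of all genes by 0.148 (log2).

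The largest rises were of genes without a count in the 4 EV early libraries of batch 1. Lgr6, a receptor of the Lgr family, had 1661 counts over the 4 late libraries there, at least 309-fold higher (adjusted p = 7.15e-11), and Itprip was at least 249-fold higher (adjusted p = 6.54e-10). Nlrp12 had 221 counts in early and 0 in late libraries of batch 2, at least 119-fold lower (adjusted p = 5.16e-07). The mitochondrial carbonic anhydrase Car5a (−5.18 ± 0.441, FDR = 1.96e-10) also fell.

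Metabolic lists of the hepatocyte fell with identity. Of the bile acid list, 19 of 20 fell, median −2.77, camera adjusted p = 4.01e-09 (p = 0.121 with estimated correlation). The rate-limiting bile acid synthesis enzyme Cyp7a1 (−4.77 ± 0.409) fell. Of xenobiotic and porphyrin genes, 22 of 22 fell, median −3.45, camera adjusted p = 8.84e-11 (p = 0.109 with estimated correlation). For fatty acid oxidation, 17 of 18 fell, median −2.14, camera adjusted p = 1.18e-11 (p = 0.109 with estimated correlation). For cholesterol synthesis, 17 of 18 fell, median −2.39, camera adjusted p = 7.56e-09 (p = 0.218 with estimated correlation), and for fatty acid and triglyceride synthesis, 14 of 15 fell (15 adjusted over the list alone), median −1.85, camera adjusted p = 1.23e-05 (p = 0.158 with estimated correlation). Of urea cycle and amino acid catabolism genes, 22 of 22 fell, median −4.30, camera adjusted p = 1.18e-11 (p = 0.149 with estimated correlation). Gluconeogenesis and glycogen genes gave 10 falls among 11, median −3.71, camera adjusted p = 2.91e-08 (p = 0.109 with estimated correlation). Coagulation and complement genes gave 21 falls among 23, median −3.33, camera adjusted p = 3.31e-16 (p = 0.109 with estimated correlation), among them prothrombin, F2 (−3.60 ± 0.185).

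Zonation, protein folding and organelle lists fell as well. Of pericentral genes, 11 of 14 fell (13 adjusted over the list alone), median −3.10, camera adjusted p = 0.00134 (p = 0.23 with estimated correlation). Of periportal genes, 2 of 14 rose and 12 fell, median −3.69, camera adjusted p = 0.00163 (p = 0.233 with estimated correlation). Cdh1 (1.37 ± 0.0809) and Sox9 (2.98 ± 0.206) rose and Hsd17b13 (−2.45 ± 0.145) fell. In the unfolded protein response, 1 of 16 rose and 14 fell, median −1.67, camera adjusted p = 0.000779 (p = 0.23 with estimated correlation). Dnajb9 (−2.13 ± 0.15) fell and the stress factor Atf3 (1.79 ± 0.517) rose. Mitochondrially encoded genes gave 12 falls among 13, median −1.58, camera adjusted p = 0.0162 (p = 0.613 with estimated correlation). Ribosomal proteins gave 19 falls among 20, median −0.61, camera adjusted p = 0.00182 (p = 0.5 with estimated correlation). In glycolysis, 5 of 14 rose and 7 fell, median −0.07, camera adjusted p = 0.0767. Gapdh (−2.06 ± 0.105) and Pgk1 (−1.99 ± 0.102) fell, and the isoforms that rose were Hk1 (4.76 ± 0.385), Pkm (3.00 ± 0.243), Pfkp (1.39 ± 0.23), Hk2 (1.00 ± 0.411) and the lactate exporter Slc16a3 (1.51 ± 0.349).

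Signalling and matrix lists rose in EV late cells. For YAP/TEAD targets, 14 of 16 rose, median 2.96, camera adjusted p = 3.59e-05 (p = 0.109 with estimated correlation). For the Notch pathway, 12 of 13 rose, median 1.85, camera adjusted p = 9.71e-06 (p = 0.109 with estimated correlation). The ligands Jag2 (6.41 ± 0.302) and Jag1 (4.18 ± 0.249) rose. TGF-beta genes gave 12 rises and 1 fall among 14, median 1.97, camera adjusted p = 0.00962 (p = 0.23 with estimated correlation), and Tgfb3 (5.59 ± 0.404) rose while the receptor Tgfbr2 (−1.09 ± 0.0939) fell. Extracellular matrix genes gave 15 rises and 1 fall among 18, median 1.87, camera adjusted p = 0.000115 (p = 0.21 with estimated correlation). The integrin Itga2 (4.89 ± 0.282) rose and fibronectin (Fn1) fell by 0.41. H3K36 methylation enzymes gave 10 rises and 2 falls among 13 (11 rose and 2 fell adjusted over the list alone), median 0.55, camera adjusted p = 0.0345 (p = 0.158 with estimated correlation). Both targeted genes rose, Kdm2a (0.61 ± 0.0738) and Nsd1 (0.27 ± 0.0666) (0.42 with DESeq2 size factors), while Nsd3 (−0.31 ± 0.0781) and Kdm8 (−0.63 ± 0.155) fell. Polycomb complexes gave 9 rises and 2 falls among 17, median 0.28, camera adjusted p = 0.0726. Bmi1 (0.81 ± 0.0701) and Cbx2 (1.28 ± 0.123) rose and Eed (−0.23 ± 0.087) and Cbx8 (−0.47 ± 0.153) fell. Of Polycomb target developmental regulators, 4 of 10 rose and 1 fell, median 2.43, camera adjusted p = 0.491 (median 1.64 with the member at 0 at its bound). Wt1 (adjusted p = 1.76e-06), Gata2 (adjusted p = 0.00406), Hoxb4 (adjusted p = 0.0125) and Sox17 (adjusted p = 0.0146) rose and Gata3 (−1.33 ± 0.416) fell.

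Among immune and growth lists, inflammatory chemokines and acute phase genes gave 12 rises and 5 falls among 19, median 0.98, camera adjusted p = 0.123. The adhesion molecule Vcam1 (2.86 ± 0.151) and the chemokine Ccl2 (2.67 ± 0.194) rose, and the acute phase genes Saa1 (−4.65 ± 0.469), Saa2 (−4.80 ± 0.417), Saa3 (−4.18 ± 0.448), Orm2 (−4.85 ± 0.441) and Lcn2 (−0.96 ± 0.204) fell. Interferon genes gave 7 rises and 8 falls among 21, median −0.02, camera adjusted p = 0.936. In the MHC list, 6 of 13 rose and 4 fell, median 0.32, camera adjusted p = 0.801. Those that fell were B2m (−1.28 ± 0.107), H2-K1 (−0.44 ± 0.0875), Psmb9 (−0.46 ± 0.141) and H2-D1 (−0.25 ± 0.0837) (2 fell without EV early 7 or EV late 5), and Cd74 (1.63 ± 0.296) rose. Proliferation genes gave 11 rises and 3 falls among 23, median 0.82, camera adjusted p = 0.388. E2f1 (−1.54 ± 0.268), Ccne1 (−1.59 ± 0.281) and Rrm2 (−1.19 ± 0.294) fell. Of p53 targets, 9 of 16 rose and 1 fell, median 0.52, camera adjusted p = 0.168. Gdf15 (−1.85 ± 0.302) fell. Fetal liver genes gave 4 rises and 3 falls among 10, median 0.35, camera adjusted p = 0.722. Peg3 (1.90 ± 0.18), Plagl1 (4.79 ± 0.467), Cdkn1c (1.66 ± 0.356) and Igf2bp1 (adjusted p = 0.0188) rose and Afp (−1.61 ± 0.28), H19 (−3.65 ± 0.663) and Spink1 (−1.92 ± 0.224) fell. Dissociation stress genes gave 8 rises and 3 falls among 17, median 0.64, camera adjusted p = 0.337. Ier3 (3.14 ± 0.338) and Egr1 (1.70 ± 0.296) rose. Hsph1 (−0.87 ± 0.304), Zfp36 (−0.58 ± 0.232) and Dnajb1 (−0.67 ± 0.265) fell (1 fell without EV early 5, EV early 6 or EV late 5, and 0 without EV late 7). With the replicate number as a block, camera also called the inflammatory (adjusted p = 0.0335), p53 and dissociation stress (both 0.05, under the threshold before rounding) lists, and the Polycomb complexes (0.0485), all as higher (p = 0.169, 0.497, 0.475 and 0.169 with estimated correlation).

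Macrophage markers were the 1 list of another cell type that camera called in EV late libraries without the block. Of macrophage and Kupffer cell markers, 16 of 17 rose and 1 fell, median 3.28, camera adjusted p = 0.0206 (p = 0.637 with estimated correlation). Csf1r (3.35 ± 0.308) and Adgre1 (3.46 ± 0.562) rose and the lysosomal gene Cd68 (−1.65 ± 0.307) fell. Endothelial markers gave 12 rises among 16, median 1.98, camera adjusted p = 0.13 (0.0464 with the replicate block, where p = 0.535 with estimated correlation), for example Kdr (2.65 ± 0.564). Stellate cell and fibroblast markers gave 8 rises among 17 (7 adjusted over the list alone), median 1.28, camera adjusted p = 0.162, for example Rgs5 (5.32 ± 0.397) (5 rose without EV early 7, EV late 1 or EV late 6). Lymphocyte markers gave 4 rises among 6, median 3.34, camera adjusted p = 0.186. The immunoglobulin genes Igkc (3.92 ± 0.511) and Jchain (3.84 ± 0.577) rose with Trbc2 (adjusted p = 1.07e-06) and Cd79a (adjusted p = 0.00708). Neutrophil markers gave 2 rises among 4, median 2.19, camera adjusted p = 0.527. Mmp9 (adjusted p = 0.00698) and Csf3r (adjusted p = 0.00877) rose. Mesothelial markers gave 6 rises and 1 fall among 8 (7 rose and 1 fell adjusted over the list alone), median 3.42, camera adjusted p = 0.189 (median 3.09 with the member at 0 at its bound), with Gpm6a (5.35 ± 0.64) and Msln (3.36 ± 0.57) higher and Lrrn4 (−1.71 ± 0.484) lower. Erythroid markers gave 3 falls among 5, median −1.95, camera adjusted p = 0.262. Alas2 (−4.25 ± 0.413), Klf1 (−1.95 ± 0.264) and Car1 (adjusted p = 0.000166) fell.

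Kdm2aKO early cells were compared with EV early cells of batch 1 (4 against 4 libraries) to show how Kdm2aKO differs at the onset of reprogramming. In Kdm2aKO 121 genes had a log2 fold change of −3 or below, while camera at the preset correlation called proliferation, p53 and fetal liver genes higher and interferon and MHC genes lower. None of these calls held with an estimated correlation (lowest adjusted p = 0.133). Nox4, a NADPH oxidase, had 0 counts in the 4 Kdm2aKO libraries against 4798 in EV, at least 1597-fold lower (adjusted p = 8.79e-13). The citrate transporter gene Slc13a5 (3 against 833 counts, 277-fold lower, 95% counting interval 94.5 to 1347, adjusted p = 9.35e-08) and Magohb (3 against 369, 123-fold, 41.7 to 598, adjusted p = 1.48e-10) followed. Large rises were of the oncogene Mycn (0 counts in EV against 80, at least 26.7-fold, adjusted p = 0.000398), Itprip (at least 23.7-fold, adjusted p = 0.00109), Elfn2 (7.98 ± 1.09, FDR = 9.66e-06) (fitted at 12.38 without EV early 1), the estrogen sulfotransferase Sult1e1 (7.48 ± 0.702, FDR = 7.37e-08) and the pheromone receptor gene Vmn2r3 (7.47 ± 1.26, FDR = 0.000371). Vmn2r3 had a log2 CPM of 7.06 in Kdm2aKO early 3 and of 2.27 to 2.86 in the others, and its log2 fold change was 4.78 without that library. In total 3175 genes passed (1541 higher and 1634 lower, 1853 of them by at least 2-fold), and 1704 passed when only the compared libraries were fitted.

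Proliferation had the smallest camera p at the preset correlation in Kdm2aKO early, though not with an estimated one: 20 of 23 rose, median 2.33, camera adjusted p = 6.47e-09 (p = 0.549 with estimated correlation). The cyclins Ccnd1 (1.71 ± 0.283) and Ccnb1 (3.67 ± 0.693) rose. Mki67, a marker of cycling cells, was at 49.7, 57.4 and 84.8 CPM in 3 Kdm2aKO libraries and at 4.13 in the library Kdm2aKO early 3, against 3.38 to 9.15 in EV. Of p53 targets, 10 of 16 rose and 1 fell (12 rose and 1 fell adjusted over the list alone), median 0.93, camera adjusted p = 3.66e-06 (p = 0.252 with estimated correlation). Gtse1 (2.83 ± 0.377) and Ccng1 (0.92 ± 0.155) rose and Ddit4l (−1.32 ± 0.313) fell. Of fetal liver genes, 7 of 10 rose, median 2.60, camera adjusted p = 6.33e-06 (p = 0.133 with estimated correlation) (median 1.69 with the member at 0 at its bound). The imprinted genes Peg3 (3.19 ± 0.246), H19 (6.50 ± 0.922) and Dlk1 (6.16 ± 1.13) rose, as did the glypican Gpc3 (3.88 ± 0.467), and 4 rose without EV early 2 or EV early 4. Interferon genes gave 10 falls among 21 (12 adjusted over the list alone), median −0.55, camera adjusted p = 3.49e-06 (p = 0.252 with estimated correlation). Kdm2aKO early 3 had the lowest mean log2 CPM of this list (2.22, others 2.98 to 3.02), and 9 members fell without it (camera adjusted p = 0.000229). The regulator Irf7 (−1.56 ± 0.141) and Oas1a (−2.43 ± 0.391) fell. MHC genes gave 10 falls among 13, median −0.63, camera adjusted p = 8.84e-06 (p = 0.252 with estimated correlation). H2-Ab1 (−4.20 ± 0.686) and Cd74 (−2.02 ± 0.408) fell.

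Hepatocyte and biliary identity were not called as lists in Kdm2aKO early cells. Of hepatocyte identity, 1 of 32 rose and 2 fell (0 rose and 0 fell adjusted over the list alone), median 0.30, camera adjusted p = 0.341. Alb (0.78 ± 0.261) rose and Serpina1c (−0.47 ± 0.154) and Cebpa (−0.66 ± 0.224) fell. Of biliary identity, 5 of 28 rose and 5 fell (10 rose and 7 fell adjusted over the list alone), median 0.14, camera adjusted p = 0.959. The members that rose were Prom1 (2.91 ± 0.505), Spp1 (1.27 ± 0.222), Ehf (2.27 ± 0.62), Sctr (2.23 ± 0.668) and Krt7 (2.56 ± 0.804), and those that fell were Wfdc2 (−3.36 ± 0.266), Krt23 (−2.31 ± 0.312), Cldn7 (−2.31 ± 0.4), Dsg2 (−0.69 ± 0.139) and Cldn4 (−1.40 ± 0.411). The number that rose was 3 without EV early 3 or 4, 2 without Kdm2aKO early 4 and 10 without Kdm2aKO early 3. YAP/TEAD targets gave 8 rises among 16 (9 adjusted over the list alone), median 1.31, camera adjusted p = 0.00234 (p = 0.252 with estimated correlation). Nt5e (1.55 ± 0.366) and Ankrd1 (2.64 ± 0.685) rose (5 rose without Kdm2aKO early 4). The Notch pathway gave 4 rises among 13, median 0.52, camera adjusted p = 0.00615 (p = 0.26 with estimated correlation). Jag2 (4.38 ± 0.47), Nrarp (3.25 ± 0.587), Notch1 (0.84 ± 0.255) and Jag1 (0.91 ± 0.294) rose (2 rose without EV early 2 or Kdm2aKO early 4). Pericentral genes gave 6 rises among 14, median 0.84, camera adjusted p = 0.00669 (p = 0.581 with estimated correlation). Oat (2.20 ± 0.419) and the Wnt target Lgr5 (2.79 ± 0.561) rose.

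The H3K36 enzymes that fell were Nsd1, Kdm2a and Nsd3 (−0.40 ± 0.103) (3 of 13 fell, median 0.03, camera adjusted p = 0.341). Stellate cell and fibroblast markers gave 4 rises among 17, median 1.42, camera adjusted p = 0.0196 (p = 0.964 with estimated correlation). Ecm1 (1.58 ± 0.317), Postn (2.98 ± 0.803), Col1a1 (2.75 ± 0.9) and Acta2 (3.19 ± 1.01) rose. That call was lost without EV early 4 (adjusted p = 0.147), Kdm2aKO early 1 (0.194) or Kdm2aKO early 4 (0.0943), and the number that rose was 2 without EV early 3, EV early 4, Kdm2aKO early 1 or 4 and 8 without Kdm2aKO early 3. Macrophage markers gave 1 rise and 1 fall among 17, median −0.61, camera adjusted p = 0.474. Csf1r (1.42 ± 0.396) rose and Cd68 (−1.59 ± 0.407) fell.

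Kdm2aKO late cells were compared with EV late cells of batch 1 (3 against 4 libraries). Camera at the preset correlation called macrophage and biliary lists lower and fetal liver and proliferation genes higher, none of them with an estimated correlation (lowest adjusted p = 0.0651). Dlk1, a fetal hepatoblast gene, had 441 counts against 2 in EV (280-fold, 95% counting interval 77.1 to 2322, adjusted p = 0.000861) and Sult1e1 211 against 2 (134-fold, 36.7 to 1115, adjusted p = 5.36e-05). H19 (5.80 ± 0.969, FDR = 0.00033) and Greb1 (4.45 ± 0.581, FDR = 1.78e-05) also rose. The largest falls were of Nox4 (−5.53 ± 0.344, FDR = 4.22e-09), the growth factor midkine, Mdk (−4.88 ± 0.457, FDR = 2.02e-07), and the macrophage genes Adgre1 (−4.80 ± 0.853, FDR = 0.000649), Siglec1 (−4.70 ± 1.16, FDR = 0.0111), Clec4f (−4.65 ± 0.946, FDR = 0.00237) and Clec7a (−4.55 ± 1.1, FDR = 0.00969). Siglec1 lost its call without Kdm2aKO late 1, Kdm2aKO late 2 or EV late 4, and Clec7a without Kdm2aKO late 1 or 2 (highest adjusted p = 0.0566 and 0.0649). Without the EV late libraries 3 and 4, chosen after seeing the data as those with the most macrophage RNA, Siglec1 (0.151), Clec7a (0.265) and Clec4f (0.0565) were lost and Adgre1 was at −3.17. In total 1754 genes passed (644 higher and 1110 lower, 1147 by at least 2-fold). The count was 1075, 976 or 1023 without Kdm2aKO late 1, 2 or 3 and 683 without EV late 3 and 4.

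Of macrophage and Kupffer cell markers in Kdm2aKO late, 14 of 17 fell (15 adjusted over the list alone), median −3.82, camera adjusted p = 3.95e-10 (p = 0.404 with estimated correlation) (9 fell without Kdm2aKO late 1 or 2, and 2 without EV late 3 and 4, where the median was −2.16 and the camera adjusted p 3e-07, or 0.587 with estimated correlation). Lymphocyte markers gave 3 falls among 6, median −2.92, camera adjusted p = 0.00169 (p = 0.297 with estimated correlation). Igkc (−3.50 ± 0.724), Jchain (−3.48 ± 0.823) and Trbc2 (−3.86 ± 0.919) fell. Endothelial markers gave 3 falls among 16 (8 adjusted over the list alone), median −1.39, camera adjusted p = 0.00113 (p = 0.646 with estimated correlation). Stab2 (−1.95 ± 0.421), Egfl7 (−1.33 ± 0.336) and Cdh5 (−3.49 ± 0.923) fell (1 without Kdm2aKO late 2). Without EV late 3 and 4, 0 lymphocyte (median −1.06, adjusted p = 0.0891) and 1 endothelial marker (−0.33, 0.13) fell. Stellate cell and fibroblast markers went the other way: 2 of 17 rose (8 adjusted over the list alone), median 1.90, camera adjusted p = 0.000316 (p = 0.646 with estimated correlation). Reln (1.82 ± 0.327) and Postn (2.96 ± 0.732) rose (1 rose without EV late 3 and 4). The MHC list gave 4 falls among 13, median −0.47, camera adjusted p = 0.00169 (p = 0.554 with estimated correlation). H2-Ab1 (−3.70 ± 0.642), H2-Eb1 (−3.78 ± 0.745), H2-Aa (−3.33 ± 0.743) and Cd74 (−1.65 ± 0.427) fell, but 1 member did without EV late 3 and 4.

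Proliferation genes in Kdm2aKO late gave 14 rises among 23 (20 adjusted over the list alone), median 1.89, camera adjusted p = 3.75e-12 (p = 0.404 with estimated correlation). Ccnd1 (1.47 ± 0.297) and Ccna2 (2.06 ± 0.503) rose. The number that rose was 7, 4 or 3 without EV late 1, 3 or 4 and 7, 9 or 3 without Kdm2aKO late 1, 2 or 3. Fetal liver genes gave 5 rises and 1 fall among 10 (6 rose and 1 fell adjusted over the list alone), median 2.02, camera adjusted p = 7.06e-07 (p = 0.0651 with estimated correlation). Peg3 (3.51 ± 0.252), Gpc3 (2.95 ± 0.458), H19 and Dlk1 (above) rose with Igf2bp1 (5.95 ± 0.95), and Spink1 (−1.28 ± 0.325) fell. Of p53 targets, 4 of 16 rose, median 0.43, camera adjusted p = 0.000867 (p = 0.457 with estimated correlation). Gtse1 (1.72 ± 0.37), Btg2 (1.31 ± 0.373), Ccng1 (0.58 ± 0.164) and Zmat3 (0.67 ± 0.198) rose (1 without EV late 1 or Kdm2aKO late 3, 2 without EV late 2, EV late 4 or Kdm2aKO late 1), and the median was 0.66 without EV late 3 and 4. Of Notch genes, 4 of 13 rose (5 adjusted over the list alone), median 0.50, camera adjusted p = 0.0101 (p = 0.404 with estimated correlation). Jag2 (1.35 ± 0.286), Hey1 (adjusted p = 0.0239), Notch2 (0.39 ± 0.112) and Nrarp (1.53 ± 0.467) rose (1 without EV late 3, Kdm2aKO late 2 or 3, 2 without EV late 1, EV late 4 or Kdm2aKO late 1). Without EV late 3 and 4, no proliferation or Notch member passed, and the camera adjusted p was 3e-07 (0.603 with estimated correlation) and 0.0891.

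Biliary identity in Kdm2aKO late gave 7 falls among 28 (1 rose and 8 fell adjusted over the list alone), median −0.55, camera adjusted p = 0.00113 (p = 0.673 with estimated correlation). The claudin Cldn7 (−2.88 ± 0.406) and Dsg2 (−0.98 ± 0.153) fell. EV late 3 was lowest in this list (mean log2 CPM 6.53, others 6.94 to 7.25). Hepatocyte identity gave 2 rises and 2 falls among 32 (3 rose and 3 fell adjusted over the list alone), median 0.27, camera adjusted p = 0.25, and 0.0271 without EV late 3 and 4 (0.981 with estimated correlation, median 0.40). Ttr (0.72 ± 0.194) and Alb (1.00 ± 0.279) rose and F9 (−1.09 ± 0.228) and the hepatocyte regulator Hnf4a (−0.52 ± 0.162) fell. Pericentral genes gave 2 rises among 14 (6 rose and 1 fell adjusted over the list alone), median 0.82, camera adjusted p = 0.011 (p = 0.646 with estimated correlation). Lect2 (1.93 ± 0.4) and Oat (1.57 ± 0.439) rose. Ribosomal proteins gave 2 falls among 20 (7 adjusted over the list alone), median −0.23, camera adjusted p = 0.00169 (p = 0.688 with estimated correlation). Interferon genes gave 3 falls among 21 (6 adjusted over the list alone), median −0.28, camera adjusted p = 0.0229 (p = 0.688 with estimated correlation). Irf7 (−0.61 ± 0.15), Oas1a (−1.47 ± 0.393) and Gbp2 (−0.82 ± 0.244) fell. The interferon call was lost without EV late 4 (0.135), Kdm2aKO late 3 (0.0639) or EV late 3 and 4 (0.13, median −0.10), and 0 members fell without Kdm2aKO late 2 or 3 or EV late 3 and 4. Coagulation genes gave 5 falls among 23 (8 adjusted over the list alone), median −0.29, camera adjusted p = 0.0266 (p = 0.971 with estimated correlation). C6 (−2.47 ± 0.512), F9, F7 (−1.13 ± 0.258), C3 (−0.55 ± 0.145) and Masp1 (−0.85 ± 0.241) fell. That call was lost without EV late 1 (0.246), EV late 4 (0.0627), Kdm2aKO late 3 (0.585) or EV late 3 and 4 (0.13, median −0.13), and 2 or 3 members fell without Kdm2aKO late 2 or 3 and 1 without EV late 3 and 4, where hepatocyte identity had 1 rise and 0 falls, pericentral genes 1 rise and ribosomal proteins 0 falls.

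**Figure D2:**
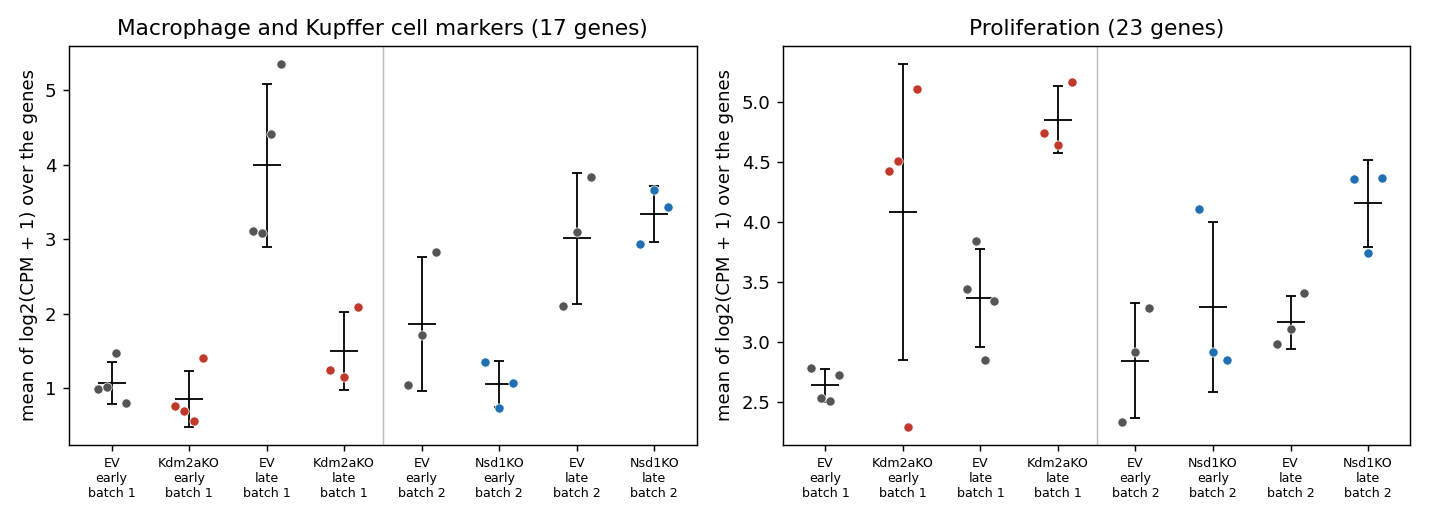
Mean log2(CPM + 1) of 17 macrophage and Kupffer cell genes and of 23 proliferation genes in each library (points), by genotype, stage and batch. Macrophage values ran from 3.08 to 5.35 in EV late of batch 1 and from 1.14 to 2.09 in Kdm2aKO late.

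Between stages, 121 genes with a log2 fold change of −3 or below in Kdm2aKO early (average log2 CPM of at least 1) had a median of −3.76 there and −1.74 in Kdm2aKO late, where 94 were called lower. The stage interaction passed for 76 of them, all with the smaller loss in late cells. Because the genes were picked by their early value, they were also picked in 2 of the 4 early libraries of each group and measured with the other 2. The median interaction was then 1.72 (145 genes) and 1.81 (139), with 60 and 73 called higher and 0 lower in late cells. Nox4 was at 17.3 ± 4.23 CPM in EV late (n = 4) and at 0.367 ± 0.246 in Kdm2aKO late (n = 3).

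**Figure D3:**
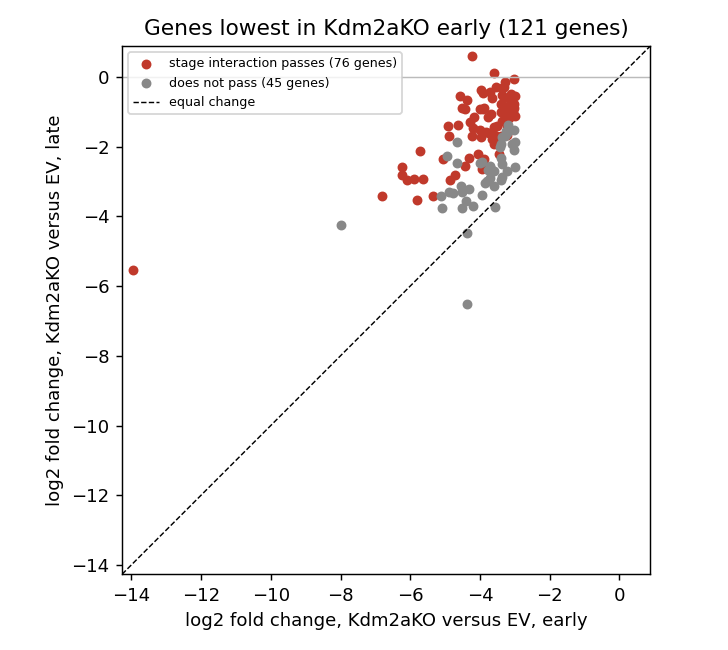
Fitted log2 fold change of Kdm2aKO against EV in early (x axis) and late cells (y axis) for the 121 genes at −3 or below in early cells, with the dashed line of equal change. The 76 genes with a called stage interaction (red) lie above the line, the other 45 are grey, the value of Nox4 rests on a group at 0, and picking genes by the x axis favours points above the line.

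Nsd1KO early cells were compared with EV early cells of batch 2 (3 against 3 libraries). Large rises were of the zinc transporter gene Slc39a5 (4.23 ± 0.452, FDR = 3.34e-06), the mucin Muc13 (3.80 ± 0.63, FDR = 0.000457) and Rassf4 (3.53 ± 0.285, FDR = 5.63e-08). Zfp57, which maintains imprints, had 0 counts against 146 in EV and was at least 41.9-fold lower (adjusted p = 9.84e-05), and Mpped2 was at least 29.6-fold lower (adjusted p = 9.84e-06). Smaller bounds were those of Nlrp9b (at least 7.75-fold, adjusted p = 0.0494), the DNA demethylase Tet1 (at least 7.46-fold, 0.0157) and P4ha3 (at least 5.17-fold, 0.0488), and Arhgap36 (−5.70 ± 0.889, FDR = 0.000249) also fell. Nlrp9b lost its call without any 1 of the 6 libraries (highest adjusted p = 0.175), Tet1 without any of the 3 Nsd1KO libraries (0.0599) and P4ha3 without EV early 6 or any Nsd1KO library (0.212). P4ha3 was also lost with an additive (0.12) or no batch term (0.172) and with DESeq2 size factors (0.0505), and Nlrp9b with no batch term (0.0546). In total 908 genes passed (381 higher and 527 lower, 640 by at least 2-fold), 599 without EV early 5 and 1519 with DESeq2.

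Fetal liver genes in Nsd1KO early gave 1 rise and 3 falls among 10, median 0.05, camera adjusted p = 0.157. Peg3 (−2.23 ± 0.296), Gpc3 (−3.16 ± 0.599) and Cdkn1c (−2.17 ± 0.586) fell and Igf2bp3 (1.98 ± 0.458) rose. Of biliary identity, 3 of 28 rose and 3 fell (4 rose and 7 fell adjusted over the list alone), median −0.38, camera adjusted p = 0.127. Krt23 (1.54 ± 0.319), Cldn7 (1.90 ± 0.404) and Cldn4 (1.59 ± 0.461) rose and Pkhd1 (−0.74 ± 0.187), Wfdc2 (−1.02 ± 0.265) and Bicc1 (−0.89 ± 0.248) fell (1 fell without EV early 5 or Nsd1KO early 1, 0 without EV early 6 or Nsd1KO early 2). Hepatocyte identity gave 2 falls among 32, median −0.04, camera adjusted p = 0.903. Among them was Ttr (−0.84 ± 0.21). The Notch ligand Jag1 (−1.54 ± 0.343) and Vcam1 (−1.18 ± 0.216) fell.

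Cholesterol synthesis and coagulation kept camera calls in Nsd1KO early whichever library was left out, although no member passed. Cholesterol genes gave 0 calls among 18, median −0.50, camera adjusted p = 0.00391 (p = 0.929 with estimated correlation), and coagulation genes gave 0 calls among 23, median 0.18, camera adjusted p = 0.0162 (p = 0.929 with estimated correlation). The MHC list gave 1 rise among 13 (6 adjusted over the list alone), median 0.31, camera adjusted p = 0.0135 (p = 0.929 with estimated correlation), that is Nlrc5 (0.66 ± 0.169), and the call was lost without EV early 5 (0.119) or 6 (0.0775). Proliferation gave 0 calls among 23, median 0.78, camera adjusted p = 0.0324 (p = 0.929 with estimated correlation), lost without EV early 5 (0.302), EV early 6 (0.0826) or Nsd1KO early 1 (0.838). Macrophage markers gave 0 calls among 17, median −1.72, camera adjusted p = 0.00391 (p = 0.929 with estimated correlation), lost without EV early 7 (0.172). Endothelial markers gave 1 rise and 1 fall among 16 (1 rose and 2 fell adjusted over the list alone), median −1.22, camera adjusted p = 0.0226 (p = 0.929 with estimated correlation), with Stab2 (2.11 ± 0.415) higher and Fcgr2b (−2.61 ± 0.582) lower, lost without EV early 6 (0.107), EV early 7 (0.053) or Nsd1KO early 2 (0.118). Stellate markers gave 1 fall among 17 (2 adjusted over the list alone), median −0.82, camera adjusted p = 0.0324 (p = 0.929 with estimated correlation), that is Rgs5 (−2.26 ± 0.515), lost without EV early 6 (0.272) or Nsd1KO early 2 (0.249).

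Nsd1KO late cells were compared with EV late cells of batch 2 (3 against 3 libraries). The hematopoietic transcription factor Tal1 stood at 22.5 ± 4.88 CPM against 0.316 ± 0.207 in EV (6.14 ± 0.93, FDR = 0.00203). Tafa2 (5.02 ± 0.978, FDR = 0.0105) (fitted at 7.98 without EV late 7), the organic anion transporter Slc22a7 (4.62 ± 0.797, FDR = 0.00326) (2.59 with no batch term) and Gabbr2 (adjusted p = 0.0066) also rose. Falls were of the imprinted noncoding RNAs Rian (−3.95 ± 0.844, FDR = 0.0199) and Meg3 (−3.93 ± 0.925, FDR = 0.0392), of Arhgap36 (−2.92 ± 0.686, FDR = 0.0392), the growth arrest gene Gas1 (−2.71 ± 0.462, FDR = 0.00312), Vav3 (−2.29 ± 0.556, FDR = 0.046) and Rasgrf1 (−2.22 ± 0.457, FDR = 0.0189). Calls were lost without EV late 5 or 6 for Tafa2 and Gabbr2 (highest adjusted p = 0.0982 and 0.0869), EV late 5 or any Nsd1KO library for Rian (0.187), EV late 5 or 6 or any Nsd1KO library for Meg3 (0.318), any EV library or Nsd1KO late 1 or 3 for Arhgap36 (0.148), and any 1 library for Vav3 (0.211) and Rasgrf1 (0.0907). With the compared libraries alone, Arhgap36 (0.0967), Gabbr2 (0.0777) and Slc22a7 (0.0541) were lost, and with no batch term Rian (0.0692) and Meg3 (0.0853). In total 174 genes passed (138 higher and 36 lower, 153 by at least 2-fold). The count was 53 to 114 with 1 library left out. It was 587 with the compared libraries alone, 426 with DESeq2 and 404 with no batch term.

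Proliferation and coagulation genes had the smallest camera p in Nsd1KO late cells. Proliferation gave 1 rise among 23 (2 adjusted over the list alone), median 1.31, camera adjusted p = 1.92e-10 (p = 0.753 with estimated correlation), that is E2f1 (1.78 ± 0.404), with Mki67 at 64.2 ± 19.3 against 24.9 ± 6.02 CPM. Coagulation gave 3 rises among 23 (13 adjusted over the list alone), median 0.70, camera adjusted p = 1.92e-10 (p = 0.753 with estimated correlation). F11 (1.61 ± 0.296), C8b (2.12 ± 0.42) and F10 (1.32 ± 0.309) rose (0 rose without EV late 5 or 6, 1 without Nsd1KO late 1). Endothelial markers gave 0 calls among 16, median −0.98, camera adjusted p = 0.000292 (p = 0.753 with estimated correlation), and these 3 calls held whichever library was left out. Hepatocyte identity gave 0 calls among 32 (1 adjusted over the list alone), median 0.64, camera adjusted p = 0.000104 (p = 0.753 with estimated correlation), lost without EV late 6 (0.0611). Bile acid genes gave 1 rise among 20 (3 adjusted over the list alone), median 0.25, camera adjusted p = 0.00394 (p = 0.753 with estimated correlation), that is Slc51b (1.92 ± 0.451), lost without EV late 6 (0.119). Biliary identity gave 1 rise among 28, median 0.13, camera adjusted p = 0.196, that is Ggt1 (2.04 ± 0.373). Of p53 targets, 0 of 16 members passed, median −0.29, camera adjusted p = 0.00738 (p = 0.753 with estimated correlation), lost without EV late 6 (0.212).

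The urea cycle, pericentral, cholesterol and stellate lists were also called in Nsd1KO late (medians 0.39, 0.43, −0.15 and −0.72, camera adjusted p = 0.0233, 0.0436, 0.0237 and 0.0153, each p = 0.753 with an estimated correlation). No member of these passed (1 pericentral member adjusted over the list alone). Without EV late 5 the adjusted p was 0.0883, 0.0978, 0.0968 and 0.0968. The urea cycle call was also lost without EV late 6 (0.659) or Nsd1KO late 1 (0.303), the pericentral call without the same libraries (0.241 and 0.338), and the stellate call without EV late 6 (0.541) or Nsd1KO late 2 (0.286). The cholesterol call was lost without EV late 7 (0.297) or Nsd1KO late 2 or 3 (0.455 and 0.257).

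The stage change was also measured within each knockout. In Kdm2aKO (3 late against 4 early libraries) 11335 genes passed (5835 higher, 5500 lower, 7336 by at least 2-fold), and in Nsd1KO (3 against 3) 11578 (5934, 5644 and 7850). Hepatocyte identity fell in all 32 members in both (median −3.72 and −3.85, camera adjusted p = 4.1e-14 and 8.72e-14), and biliary identity rose in 24 and 26 members, the keratins Krt8 and, in Kdm2aKO, Krt18 falling (median 2.55 and 3.21, camera adjusted p = 1.86e-07 and 1.19e-09). The lowest adjusted p of any list with an estimated correlation was 0.161 in Kdm2aKO and 0.107 in Nsd1KO. In Nsd1KO, macrophage markers gave 16 rises among 17 (16 rose and 1 fell adjusted over the list alone), median 3.55, camera adjusted p = 0.0133 (p = 0.579 with estimated correlation). In Kdm2aKO they gave 2 rises and 1 fall among 17, median 1.77, camera adjusted p = 0.239. In Kdm2aKO, Nox4 rose (at least 12.8-fold, adjusted p = 1.37e-05). In Nsd1KO, Zfp57 was at least 472-fold higher in late cells (adjusted p = 5.81e-10) and Tet1 at least 395-fold (2.18e-09), and the Wnt inhibitor Notum (−4.82 ± 0.5, FDR = 1.35e-08) fell.

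The genotype by stage interaction asks whether a knockout's difference from EV differed between late and early cells. For Kdm2aKO 742 genes passed (391 with a higher and 351 with a lower effect in late cells). Nsd1 was less reduced in late cells (0.66 ± 0.128, FDR = 0.00315), and Kdm2a did not pass (0.31 ± 0.142, FDR = 0.275). Kcnj8 (4.83 ± 0.579, FDR = 9.96e-06) and Tnfsf12 (4.03 ± 0.224, FDR = 2.98e-11) were also relatively higher in late cells. The macrophage effect was lower in late cells (camera adjusted p = 1.33e-06). That call held whichever library was left out, although 0 members passed without EV late 3 and 4. Camera also called the biliary (0.00762), YAP/TEAD (0.0039), endothelial (0.0105) and ribosomal (2.41e-05) lists lower and the interferon list (0.00762) higher. All 6 had p = 0.958 with estimated correlation. The replicate block gave 6 calls too but changed 4. Calls were lost without EV early 4 (0.0695) or Kdm2aKO early 4 (0.147) for biliary, EV late 4 (0.111), Kdm2aKO early 4 (0.147), Kdm2aKO late 2 (0.0776) or EV late 3 and 4 (0.367) for endothelial, and Kdm2aKO early 3 (0.125) for interferon genes. The count was 473 without Kdm2aKO late 2, 452 without EV late 3 and 4, 416 with the compared libraries alone and 1291 with DESeq2. Another split of the same samples reached 1129. For Nsd1KO 133 genes passed (116 and 17), such as Parm1 (4.44 ± 0.485, FDR = 3.34e-05) relatively higher in late cells and Fhl1 (−3.71 ± 0.599, FDR = 0.00225) lower. Camera called the macrophage, hepatocyte, biliary, urea cycle and bile acid lists higher and dissociation stress lower (adjusted p = 0.00124, 0.0125, 0.0207, 0.0207, 0.0215 and 0.0326, each p = 0.916 with estimated correlation). Each call was lost without 1 or more of EV early 6 and 7, EV late 6 and the Nsd1KO libraries (highest adjusted p = 0.0781, 0.177, 0.18, 0.282, 0.162 and 0.974). Other splits of the same samples reached up to 1066 calls. The Nsd1KO count was 68 to 160 with 1 library left out.

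The difference between both knockout effects was tested at each stage. In early cells 2408 genes passed (1139 with the higher value in Kdm2aKO and 1269 with the lower), such as Elfn2 (10.07 ± 1.81, FDR = 0.000406) and Tmem200b (−7.29 ± 0.559, FDR = 2.46e-09). Of fetal liver genes, where a rise is a higher effect in Kdm2aKO, 5 of 10 rose, median 2.27, camera adjusted p = 6.11e-06 (p = 0.122 with estimated correlation). Peg3 (5.42 ± 0.385), Gpc3 (7.04 ± 0.757), H19 (6.49 ± 1.22), Cdkn1c (2.61 ± 0.76) and Dlk1 (6.06 ± 1.76) rose (3 rose without Nsd1KO early 3). p53 targets gave 9 rises among 16, and MHC and interferon genes 7 falls each among 13 and 21 (camera adjusted p = 1.33e-05, 4.75e-07 and 1.33e-05, and p = 0.247, 0.18 and 0.247 with an estimated correlation; adjusted over the list alone, 10, 10 and 7). In late cells 727 passed (147 and 580), such as Sorcs1 (8.56 ± 1.33, FDR = 0.000509), Tal1 (−7.69 ± 1.36, FDR = 0.00174) and Mdk (−6.16 ± 0.591, FDR = 1.07e-06). The fetal liver list gave 3 rises among 10 (5 adjusted over the list alone), median 2.54, camera adjusted p = 2.2e-08 (p = 0.0255 with estimated correlation), namely Peg3 (4.32 ± 0.362), Gpc3 (4.88 ± 0.689) and H19 (5.00 ± 1.31, FDR = 0.0313), and this was the 1 list of any comparison called with an estimated correlation. That call was lost without Nsd1KO late 1 (0.0505), 2 (0.0546) or 3 (0.0725) or without EV late 3 and 4 (0.0661). H19 was lost without EV late 3, 4, 5 or 7, Kdm2aKO late 1 or 2, or Nsd1KO late 2 or 3 (highest adjusted p = 0.0943). The late count was 408 to 742 with 1 library left out and 450 without EV late 3 and 4.

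In early cells 66 genes were higher and 113 lower in both knockouts and 186 went opposite ways, where 30.5, 44.7 and 74.4 would be shared by independent lists. In late cells the counts were 24, 8 and 18 (4.61, 2.07 and 9.15).

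The hepatocyte minus biliary score was 6.46 ± 0.845 (SD) in Kdm2aKO early and 6.54 ± 1.03 in EV early of batch 1 (n = 4 each, difference −0.08, exact permutation p = 0.886, adjusted 0.886). Kdm2aKO late scored 0.46 ± 0.856 (n = 3) against −0.40 ± 0.623 (n = 4, difference 0.85, exact permutation p = 0.257, adjusted 0.514). Nsd1KO early scored 6.27 ± 0.855 against 5.75 ± 0.301 (n = 3 each, exact permutation p = 0.6, adjusted 0.72), and Nsd1KO late −0.96 ± 0.353 against −1.45 ± 0.839 (exact permutation p = 0.5, adjusted 0.72). EV late minus early was −6.94 in batch 1 (exact permutation p = 0.0286, adjusted 0.172) and −7.20 in batch 2 (p = 0.1, adjusted 0.3). These are the smallest p that exact two-sided tests of these sizes can give, so after adjustment no score test could pass.

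**Figure D4:**
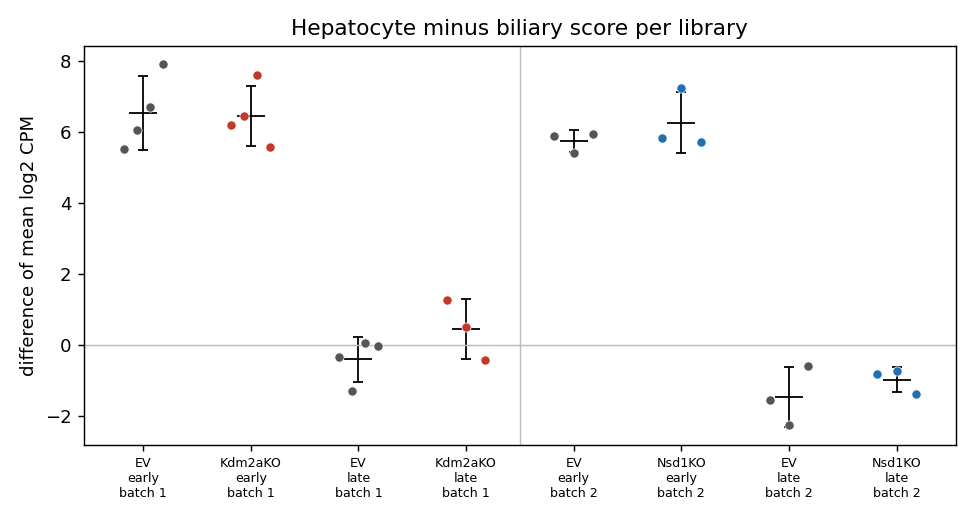
Hepatocyte minus biliary score (difference of mean log2 CPM) of each library (points) with the mean and SD (bars) by genotype, stage and batch. Early libraries average 5.75 to 6.54 and late libraries −1.45 to 0.46.

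Each knockout effect was also correlated across genes, which are not independent replicates, with the EV stage change of the other batch. For Kdm2aKO the correlations were 0.154 (Pearson) and 0.121 (Spearman) in early and −0.10 and 0.035 in late cells. Pearson values as large in size came from 10 and 17 of 34 other splits of the same libraries. For Nsd1KO they were −0.236 and −0.162 in early cells, where 0 of 9 other splits were as large (range −0.227 to 0.172), and −0.062 and −0.010 in late cells, where 4 of 9 were.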

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

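Tests chosen only after their result was seen were those of a linked variant, of a single share of late cells without the loss, the 3 on macrophage markers and the 2 on proliferation genes, together with the fit without EV late 3 and 4 and the choice of genes in part of the early libraries.

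In Kdm2aKO early, 121 genes had a log2 fold change of −3 or below (median −3.76), for which the design offers an effect of the Kdm2a guide as a hypothesis, not itself tested. CpG-rich 5' ends do not mark them, since the CpG ratio of their first 300 transcript bases had a median of 0.601 (118 genes) against 0.679 in random sets (95th percentile 0.735). A single share of late cells without the loss is argued against by the late levels of the 46 genes at −4 or below, 7.32 to 52.7% of EV between the 10th and 90th percentiles, a 7.21-fold range (chi-square test of heterogeneity, p = 2.32e-109), although these genes were picked by their early value. A virus-borne guide brings no linked variant, but a strain difference cannot be told apart from its effect. The genes lay on 19 chromosomes, with 8 neighbouring pairs (95th percentile in 10000 random sets 7). The stage interaction (median 2.09, raised by the choice of genes, 1.72 and 1.81 in libraries not used for it) leaves a strain variant acting by stage open.

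Macrophage markers were lower in Kdm2aKO late, with Cd5l at 4.88 ± 4.81 against 79.4 ± 64.1 CPM in EV and Clec4f at 2.35 ± 1.01 against 58.8 ± 54.3, although Csf1r stood at 71.1 ± 2.06 against 77.6 ± 31.1. A lower share of all non-parenchymal cells is argued against, because the median of stellate markers was 1.90 while those of endothelial and lymphocyte markers were −1.39 and −2.92. The markers rose and fell together over EV late libraries, at a mean correlation across libraries of 0.942 (95th percentile 0.0848 in 2000 random sets), so macrophages or their RNA in those libraries may account for the pattern despite the sort on GFP and CD24. Fewer macrophages in the Kdm2aKO livers cannot be told apart from this, as the early median of −0.61 lay between the values that either answer needed.

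Proliferation genes were higher in Kdm2aKO early. Late cells in the early sort are argued against, since these genes would need a median share of 69.2% late cells and 146 abundant late genes allowed 2.27% (upper quartile 3.55%). A single library is argued against as well, with 18 to 22 members called whichever of the 4 was left out, although Kdm2aKO early 3 lay at 4.13 CPM of Mki67 and the others at 49.7 to 84.8. An effect of the guide on proliferation remains a hypothesis, and a difference between livers in the phase of regeneration was not tested.

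Of 190 groups of values, 14 held a library far from the others, where chance gives about 1 in 20. Kdm2aKO early 3 was lowest in mean log2 CPM of the interferon list (2.22, others 2.98 to 3.02) and highest in the xenobiotic list (8.05, others 7.71 to 7.73) and in Vmn2r3 (7.06, others 2.27 to 2.86). EV late 3 was lowest in the biliary list (6.53, others 6.94 to 7.25) and in Greb1 (−0.45, others 1.06 to 2.16) and highest in Sult1e1 (−3.47, others −4.41). EV early 4 was highest in the coagulation list (9.96, others 9.52 to 9.60), EV early 3 lowest in Magohb (1.22, others 1.92 to 2.19), and EV early 6 highest in P4ha3 (−1.22, others −4.41 to −3.27). EV early 2 was highest in Vmn2r3 (−0.50, others −4.41 to −2.997) and lowest in Tafa2 (−4.41, others −1.76 to −0.16). Also lowest, at −4.41, were Acot6 in Kdm2aKO early 2 (others −3.55 to −3.53), H19 in EV late 2 (−1.07 to 1.28) and Fitm1 in EV late 6 (−2.10 to −1.04).

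The difference of Kdm2aKO from EV differed between stages for 742 genes. Fitted log2 differences were 8.43 ± 1.04 (SE) for Nox4, 4.83 ± 0.579 for Kcnj8, 4.81 ± 0.381 for Plekhb1, 4.03 ± 0.224 for Tnfsf12, 3.96 ± 0.513 for Chadl and 3.71 ± 0.584 for Fut10. They were −8.76 ± 1.39 for Prkar1b, −7.94 ± 1.73 for P4ha3, −6.82 ± 1.76 for B4galt4, −6.68 ± 1.16 for Ccdc8, −5.88 ± 1.1 for Faxc and −5.87 ± 1.32 for Fkbp10. Those of Nox4, Prkar1b, P4ha3, B4galt4, Ccdc8, Faxc and Fkbp10 rest on a group with 0 to 3 counts and are no bounds. P4ha3 was lost without Kdm2aKO early 1 (adjusted p = 0.084). B4galt4 was lost without EV early 1 (0.0543), 2 (0.0598), 3 (0.0545) or 4 (0.0514), Kdm2aKO early 1 (0.0818) or 4 (0.0536), or Kdm2aKO late 2 (0.0609) or 3 (0.0655), and with the compared libraries alone (0.064). With an additive or no batch term B4galt4 (0.489 and 0.667) and P4ha3 (0.0826 and 0.123) were lost, and with none Fkbp10 (0.118). Without EV early 2, Faxc was fitted at −8.82 and Fkbp10 at −9.34.

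That of Nsd1KO differed between stages for 133 genes. The differences were 7.58 ± 1.5 for Zfp57 and 7.35 ± 1.1 for Mpped2, both resting on a group at 0 counts, 4.64 ± 0.774 for Nrep, 4.44 ± 0.485 for Parm1, 4.09 ± 0.765 for Bmp7 and 4.07 ± 0.799 for Arnt2. Lower in late cells were Fhl1 (−3.71 ± 0.599), Stab2 (−2.84 ± 0.574), Cdh17 (−2.80 ± 0.502), Rassf4 (−2.66 ± 0.373), Slc39a5 (−2.48 ± 0.587) and Ptgds (−2.48 ± 0.508). With the replicate block, Zfp57 (adjusted p = 0.0533) and Ptgds (0.0868) were lost. Zfp57 was also lost without Nsd1KO early 2 (0.0581), Ptgds without EV early 5 (0.0621) or Nsd1KO late 1 (0.057) or 3 (0.052), and Stab2 without EV early 5 (0.0518), EV late 6 (0.0529) or 7 (0.0571), or Nsd1KO late 1 (0.057) or 3 (0.0567), and with an additive (0.158) or no batch term (0.179). With the compared libraries alone Ptgds (0.0684) and Slc39a5 (0.0605) were lost, the latter also with DESeq2 size factors (0.0554). Without Nsd1KO early 1, Bmp7 was fitted at 8.90. Slc39a5 was lost without EV early 5 (0.124), 6 (0.109) or 7 (0.0537), EV late 5 (0.112) or 7 (0.164), Nsd1KO early 1 (0.121), 2 (0.0545) or 3 (0.0832), or Nsd1KO late 2 (0.121) or 3 (0.132).

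The knockout effects differed for 2408 genes in early cells. Higher in Kdm2aKO relative to Nsd1KO were Ctnna2 (12.41 ± 2.51), P4ha3 (10.66 ± 2.42), Elfn2 (10.07 ± 1.81), Mycn (9.57 ± 2.02), Itprip (8.999 ± 1.95) and A2m (8.61 ± 1.87). Lower were Nox4 (−12.19 ± 0.769), Slc13a5 (−10.01 ± 1.01), Serpina4-ps1 (−8.28 ± 1.61), Tmem200b (−7.29 ± 0.559), Adamtsl5 (−6.51 ± 0.739) and Arhgap4 (−6.15 ± 0.406). The values of Ctnna2, P4ha3, Mycn, Itprip, A2m, Nox4 and Slc13a5 rest on a group with 0 to 3 counts. P4ha3 was lost with an additive (adjusted p = 0.0509) or no batch term (0.0918) and Itprip with none (0.0802).

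In late cells 727 genes differed between the knockout effects. Higher were Sorcs1 (8.56 ± 1.33), Grik3 (7.17 ± 1.05), Themis (6.72 ± 1.41), Rian (5.31 ± 1.08), H19 (5.00 ± 1.31) and Rasgrf1 (4.99 ± 0.619). Lower were Serpina4-ps1 (−10.68 ± 2.69, with a group at 0 counts), Tal1 (−7.69 ± 1.36), Mdk (−6.16 ± 0.591), Slc13a5 (−6.03 ± 1.07), Clec4f (−5.67 ± 1.23) and Aqp7 (−5.44 ± 0.705). Themis was lost without EV late 7 (adjusted p = 0.0552) and Clec4f with an additive (0.219) or no batch term (0.0518). Without EV late 3 and 4, Clec4f (0.0778), H19 (0.156) and Serpina4-ps1 (0.187) were lost. H19 was lost without EV late 3 (0.0611), 4 (0.0618), 5 (0.0779) or 7 (0.0598), Kdm2aKO late 1 (0.0669) or 2 (0.0674), or Nsd1KO late 2 (0.0732) or 3 (0.0943). Serpina4-ps1 was lost without EV late 4 (0.0745), 5 (0.0725) or 6 (0.0712), Kdm2aKO late 1 (0.053), 2 (0.0739) or 3 (0.0631), or Nsd1KO late 1 (0.0638), and with no batch term (0.0567).

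Other splits of the same samples were counted, the real one included. Chance was excluded for EV late against early (13664 genes, highest other split 10837, 1 of 100 splits as large), where the 4 others that parted every replicate pair reached at most 3738. It was excluded for Kdm2aKO early (3175 against 721, 1 of 35), Kdm2aKO late (1754 against 499, 1 of 35) and the Kdm2aKO stage change (11335 against 8643, 1 of 35). The real split was highest too for the differences between knockouts (early 2408 against 1271, late 727 against 82, 1 of 100 each). As these splits mixed each knockout with EV, either effect alone could give this. The share was under 0.05 for the Kdm2aKO interaction too (742 genes, 2 of 100), but the other split gave 1129. That split kept the early genotypes apart and mixed the late ones, so it holds the early difference. Chance was not excluded for the Nsd1KO interaction (133 against 1066, 7 of 100), where the split with several times the real count joined EV early to Nsd1KO late, so it adds the differences of both stages. Splits were too few for a share under 0.05 (10 each) for Nsd1KO early (908, highest other 0), Nsd1KO late (174 and 0) and the Nsd1KO stage change (11578 and 1).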

How the results depend on the processing

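The fit without EV late 3 and 4, the controls highest in macrophage markers, and the estimated correlation with the replicate block were chosen only after the data were seen. Over the settings other than single libraries left out, 94 of 116 summary values stayed within 1.5 times or on their side of the threshold and 22 moved. Of 1096 values of the targeted genes and the largest rises and falls, 1050 kept direction and call. Another 44 lost the call, 2 gained it (Kdm2a in Kdm2aKO late) and 0 reversed. The cause of a change was not tested unless given.

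With an additive batch term the Nsd1KO interaction held 254 genes. With no batch term the counts were 404 for Nsd1KO late, 235 for the Nsd1KO interaction, and 3614 and 1540 for the difference between knockouts in early and late cells. With the compared libraries alone they were 1704 for Kdm2aKO early, 587 for Nsd1KO late, 416 and 233 for the Kdm2aKO and Nsd1KO interactions, and 1428 and 1633 for the early and late differences; fewer libraries then set the spread. DESeq2 called 1519 genes for Nsd1KO early, 426 for Nsd1KO late, 1291 and 386 for the Kdm2aKO and Nsd1KO interactions, and 1244 for the late difference. Without EV late 3 and 4 the counts were 683 for Kdm2aKO late, 452 for the Kdm2aKO interaction and 450 for the late difference. Of 407 list tests, camera called 135, 129 with the additive term, 1 with an estimated correlation, and fry called 123.

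Replicate numbers paired early and late libraries of EV and Nsd1KO. As a replicate block they gave 13672 genes in EV, 11713 in Nsd1KO and 118 for the Nsd1KO interaction. Besides the calls given with their results, camera then added the inflammatory (adjusted p = 0.0138), endothelial (0.0138) and stellate (0.0253) lists in Nsd1KO and the interferon (0.0447), xenobiotic (0.0215), cholesterol (0.0232) and ribosomal (0.0198) lists to the Nsd1KO interaction, none with an estimated correlation (lowest adjusted p of any list 0.102 and 0.832); the block changed no other call there. Kdm2aKO numbers do not pair all libraries: same-numbered early and late ones correlated at −0.0135 to 0.130, and late 3 with early 4 at 0.155. Their block gave 11128 genes between stages and 720 for the interaction, without P4ha3, B4galt4 and Fkbp10 (0.102, 0.0942 and 0.122), changed 7 list calls, and gave 1166 with late 3 paired to early 4 by adjacent library names, where each of 3 pairs correlated at 0.118 or more. Numbers shared with EV (correlations of −0.204 to 0.0954) gave 2562 genes in Kdm2aKO early and 1071 in late, without Siglec1 (0.0596).

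Leaving out 1 library gave 976 to 1668 genes for Kdm2aKO late (1075, 976 and 1023 without its libraries 1, 2 and 3), 473 (Kdm2aKO late 2) to 973 for the Kdm2aKO interaction and 599 (EV early 5) to 746 for Nsd1KO early. The late difference ran from 408 to 742 (Kdm2aKO late 2 and 3: 408 and 465, EV late 5 and 6: 434 and 443, Nsd1KO late 2: 484). The Nsd1KO interaction ran from 68 to 160 (EV early 5: 87, EV late 5, 6 and 7: 77, 68 and 76, Nsd1KO early 2: 83, Nsd1KO late 1 and 3: 83 and 70), and Nsd1KO late from 53 to 114 (EV late 5, 6 and 7: 53, 59 and 114, Nsd1KO late 1, 2 and 3: 89, 93 and 85). Within 1.5 times lay Kdm2aKO early (2627 to 3186), the early difference (lowest 1956) and the stage changes of EV (13355 to 13611), Kdm2aKO (10308 to 11105) and Nsd1KO (10649 to 11145). The score difference ranged in Kdm2aKO from −0.46 to 0.37 early and 0.44 to 1.30 late. In Nsd1KO it ranged from 0.03 to 0.80 early and 0.09 to 0.92 late, and no test could pass. With list medians it was 0.76, −0.81 and −0.10 in Kdm2aKO early, Nsd1KO early and Nsd1KO late, opposite in sign and not called. Genes with 0 to 3 counts in a group limit a fold to a bound or a wide interval at this depth.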

Other observations

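Tests chosen only after their result was seen were those of sex-biased members already looked at, of female animals and of imprinted genes in Kdm2aKO late; 8 hypotheses were tested here, on genes that are not independent replicates.

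Genes known as female-predominant in mouse liver were higher in Kdm2aKO early cells. Of 20 such genes looked at first, 12 rose and 2 fell, and of 14 male-predominant genes 0 rose and 6 fell, a difference in mean log2 fold change of 3.95 (permutation p = 8e-05). Among members not looked at before, 5 of 8 female-predominant genes rose and 1 fell and 0 of 8 male-predominant genes rose and 4 fell (difference 2.32, permutation p = 0.0201). Cyp2b9 stood at 98.8 ± 46.6 CPM against 4.87 ± 2.92 in EV early, and Sult1e1 at 33.6 ± 18.6 against 0.188 ± 0.147 (SD, n = 4 each). In late cells 7 of the first 20 rose and 1 fell, and 4 of the 14 fell; of the members not looked at before, 3 of 8 rose and 1 fell, and 0 of 8 male-predominant genes fell (median 0.37, the opposite direction). Female animals are argued against, because the lowest Y-linked level of a Kdm2aKO early library was 84.5% of the EV early mean. A shift towards female-predominant expression may follow the guide, as a hypothesis.

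X-linked genes were lower in Nsd1KO early more often than others, 51 of 558 (9.14%) against 2.79% (odds ratio 3.5, Fisher's exact p = 1.27e-12), with Tceal8 (−2.10 ± 0.184) and Igsf1 (−4.27 ± 0.414) having the smallest p. That X-linked genes are late-stage genes is argued against as the whole explanation, since 26 of 218 X-linked genes higher in EV late of batch 1 were lower (11.9%) against 312 of 5620 others (5.55%, Fisher's exact p = 0.000504). Over libraries, mean log2 CPM of X-linked minus other genes differed by −0.28 in Nsd1KO and −0.27 in Kdm2aKO early. Exact permutation p was 0.1 and 0.0286, each the smallest possible. The X-linked share was also higher in Kdm2aKO early (12.7 against 9.04%) and late (10.2 against 6.18%), and whether the knockouts differ was not tested. The list of 26 imprinted genes left out those already named, such as Peg3, H19, Dlk1 and Cdkn1c. Called were 6 in Kdm2aKO early (matched random median 5, 95th percentile 8) and 4 in Nsd1KO early (1 and 4), neither above that percentile. In Kdm2aKO late 9 were called (95th percentile 5), of which Usp29, Peg10, Igf2r, Airn and Ndn rose and Grb10, Phlda2, Slc22a18 and Ppp1r9a fell.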
